A study of Mus musculus with 6 samples.

How the data were processed

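RNA from whole bone marrow was measured on 6 Affymetrix mouse arrays, 3 control and 3 induced, each from 3 pooled mice. Groups were taken from the labels. Per the labels' protocols, RNA was extracted with Trizol, 10 ug went into amplification, and the fragmented product was labelled with biotin. The authors' deposited value table holds a linear signal intensity for each of 45101 probe sets, made with MAS5 per the submitters' processing notes, with version and scaling target not given in the sources used here. Signals were rounded to 1 decimal, and their 2% trimmed mean differed between arrays (1.67 to 2.36). The authors' deposited ANOVA table gives an unadjusted p-value and a linear ratio of control over induced per probe set, per the file headers; the values that went into it are not stated. The authors' deposited list holds the 1144 probe sets of that table with at least a 2-fold difference.

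Signals were used as deposited and transformed as log2(signal + 16). Because 76.9% of all signals were 2 or lower, this pseudocount is large for the table, and fold changes on that scale understate the change of a gene; the text therefore leads with mean signals and their ratios. Probe sets with a mean log2 value over the 30th percentile were tested, and 64 control probe sets were left out. The test was lmFit and eBayes in limma 3.58.1 (R 4.3.3), induced minus control, with Benjamini-Hochberg adjustment over 31523 probe sets. With 3 pools a group, p-values measure the spread between pools.

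Gene symbols came from the authors' deposited ANOVA table, where 38011 probe sets have 1 symbol, 1280 several and 5746 none; a gene was named only from a probe set with 1 symbol. Of 20678 distinct symbols, 16590 were current in a RefSeq mouse gene table and 1723 were updated through a synonym there; other symbols were kept. That table was used for names only. Each gene was represented by its probe set with the highest mean log2 value. A signal of 2, the highest that 27 control probe sets for bacterial transcripts reached on any array, was taken as background after the data were seen. Where all arrays of 1 group were at or under it, the other group's mean over 2 is given as "at least".

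Gene lists, 48 in all, the named gene rule and the tests were fixed before the data were examined. Lists with at least 5 tested members (46) were tested with camera at its preset correlation of 0.01, with an estimated correlation, and with fry. The rule named Jun, sex-linked genes, the 12 largest rises and falls by log2 change of (signal + 16) among called genes without overlap, the 4 members with the smallest p of each called list and 3 of the collagen, AP-1 family, matrix and profibrotic lists; the text gives part of these, and some genes that the rule names are not reported here. Hbb-b2, and the globin and further genes of the closing section, lie outside the rule and were chosen after their values were seen.

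Alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter and a 60th percentile filter, an intensity trend, array weights, the replicate number as a block, a plain per-gene test, adjusted p under 0.1, the authors' p-values, the mean of all probe sets of a gene, and leaving out each array. Scaling to 1 trimmed mean, scaling to a trimmed mean of 500, and scaling to 1 median of probe sets with mean signal over 10 were added after seeing the data. Values of single array measures were compared with an exact permutation test.

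The scripts were tested on simulated data. Signals of the 31523 probe sets were drawn from their means and spreads, each independently of the others. Of these, 200 probe sets with a mean signal over 10 were changed. The test recovered 36% of the 100 changed 2-fold and 75% of the 100 changed 4-fold, and 5.93% of its calls were false. A simulated shift of the ribosomal list by 1 on the log2 scale was called, with 0 of the other lists called. Since genes were drawn independently, the simulation does not show how often correlated genes give false calls. Figures were drawn with matplotlib 3.10.9.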

Results

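Gene expression was measured in whole bone marrow of c-Jun inducible mice on Affymetrix mouse arrays. c-Jun, encoded by Jun, is a subunit of the AP-1 transcription factor. The 3 control arrays came from mice without induction (day 0), and the 3 induced arrays from mice given doxycycline, the inducing antibiotic, at 1 mg/ml in the drinking water for 24 h (day 1). Each array held RNA pooled from 3 mice aged 8 weeks, and the labels call the arrays of a group biological replicates. The comparison asks which genes of the marrow differ within a day of c-Jun induction, in a study whose title concerns fibrosis. No array of mice given doxycycline without induction of c-Jun was analysed here. The antibiotic, the induced gene and the day given in the labels therefore differ between the groups together. The share of Gapdh signal read at the 5' end, given below, differs along with them, which concerns all genes compared. The summed signal of an array was 205858 ± 14351 in controls and 246508 ± 28724 in induced arrays (SD, n = 3 each), and 2636 ± 227 and 3101 ± 267 probe sets had a signal over 10. Control 2 had 346 signals of 0, against 4653 to 7818 in the other arrays; without it 879 probe sets were called higher and 302 lower. The number of arrays limits the precision. Below, values of a gene are the mean ± SD of the deposited signal over 3 arrays, in arbitrary units, and ratios are ratios of these means. Largest rises and falls are ranked by the log2 change of (signal + 16), a scale on which dim genes move less, and by ratio the order differs.

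Jun itself was read near background by both of its probe sets. The brighter one had a signal of 1.13 ± 0.90 in controls and 2.80 ± 1.41 in induced arrays, a log2 change of 0.13 with a standard error of 0.07 on the log2(signal + 16) scale (limma, adjusted p = 0.446). The other had 1.6 ± 0.78 and 1.00 ± 0.85 (adjusted p = 0.810). The authors' deposited table gave an induced over control ratio of 1.74 for the brighter probe set, with an unadjusted p-value of 0.00663. Whether the transgene carries the sequence that these probe sets read is not known here, so their values neither support nor contradict the labels.

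After 24 h of induction, the largest rises on that scale included the eosinophil genes Ear1 and Prg2, the immediate early genes Dusp1 and Fos, and Spp1. Ear1, an eosinophil-associated ribonuclease, rose from 7.67 ± 2.61 to 94.2 ± 6.69, and Prg2, the eosinophil major basic protein, from 14.9 ± 4.1 to 124.2 ± 19.5. Dusp1, a phosphatase that turns off MAP kinases, rose 7.30-fold, from 19.0 ± 5.90 to 138.7 ± 23.5. Fos, the partner of c-Jun in AP-1, rose from 2.53 ± 2.66 to 49.6 ± 12.2. Spp1, which encodes osteopontin, rose from 2.57 ± 2.15 to 33.8 ± 5.97. The proteoglycan core Srgn rose 4.74-fold, the calcium-binding S100a6 3.45-fold, Lyrm4 5.23-fold, Fxyd5 3.81-fold, the cathepsin inhibitor Cstb 3.82-fold, the chemokine Ccl9 3.63-fold and the lectin receptor Clec4d 3.72-fold.

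The largest falls on the log2(signal + 16) scale included Tfrc, Ahsp and Slc4a1 of the erythroid list and Slc25a37 of the haem list. Apol11b fell from 214.4 ± 12.9 to 9.17 ± 1.77, and Xpo7, a nuclear export receptor, from 651.5 ± 84.1 to 84.5 ± 18.6. Tfrc, the transferrin receptor that brings iron into the cell, fell from 273.5 ± 24.8 to 40.3 ± 4.76. Ahsp, the chaperone of alpha globin, fell from 363.7 ± 45.7 to 71.0 ± 18.2, and Slc4a1, the anion exchanger of the red cell membrane, from 394.1 ± 55.6 to 105.4 ± 6.29. The mitochondrial iron importer Slc25a37 was 7.62-fold lower, Ift140 8.68-fold, the interferon-stimulated gene Rsad2 4.13-fold, Pigq 3.91-fold and the proliferation marker Mki67 3.57-fold. The glycine transporter gene Slc6a9 fell from 32.7 ± 4.71 to background, at least 16.4-fold.

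**Figure D1:**
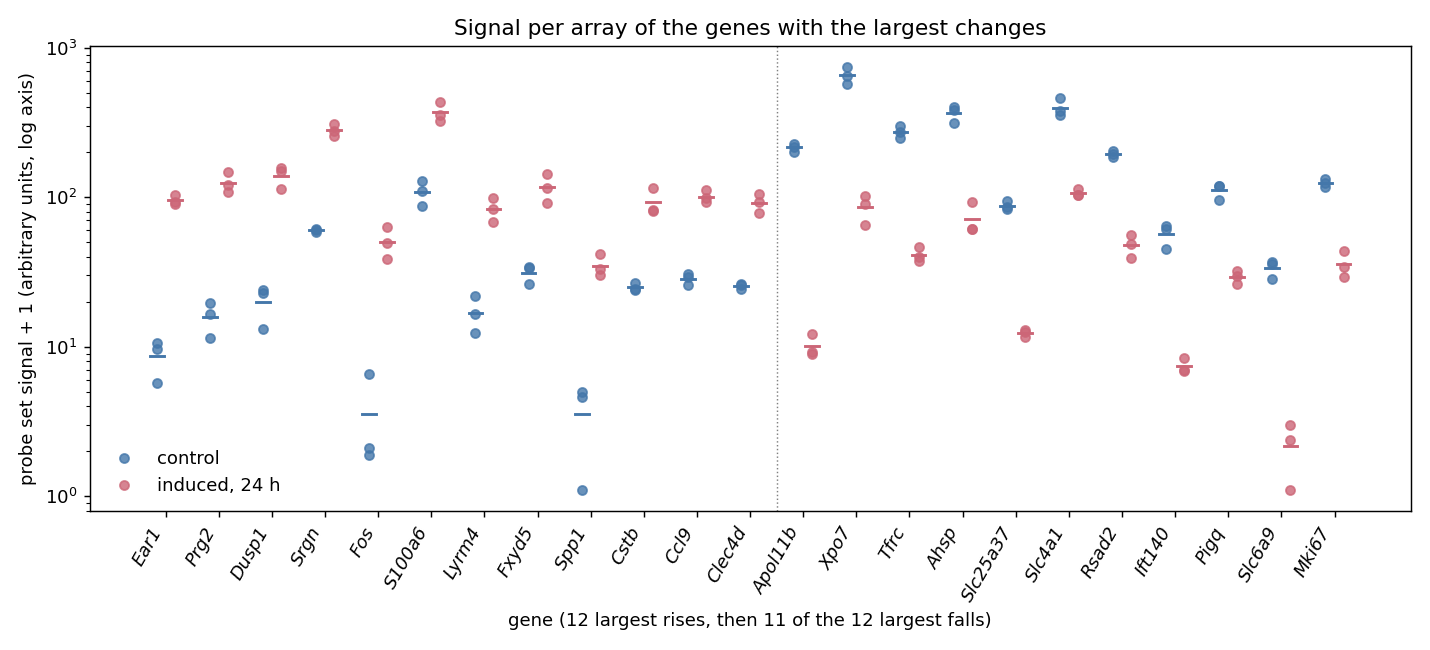
Deposited signal plus 1 (arbitrary units, log axis) of the 12 genes with the largest rises, left of the dotted line, and 11 of the 12 with the largest falls, right of it, ranked by the log2 change of (signal + 16). Each point is 1 array, blue for control and red for induced at 24 h, and each short line is the mean of 3 arrays. Only genes whose groups do not overlap were eligible.

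Of 31523 probe sets tested, 1320 were higher and 427 lower in induced arrays at an adjusted p under 0.05 (limma). By gene, 835 were higher and 296 lower out of 16239, and 485 and 196 of these had means that differed at least 2-fold. No called probe set had overlapping groups, and over all probe sets tested the groups did not overlap in 18.0%, against 10% by chance. The split depended on scaling between arrays. As deposited, 75.6% of the called probe sets were higher, against 53.3% after quantile normalization (974 higher, 853 lower). The 2868 probe sets with a mean signal over 10 had a median log2 change of 0.24 as deposited and 0.06 after quantile normalization. As plain ratios of the deposited means, without the pseudocount, their median log2 ratio was 0.41, against 0.18 by the authors' ratios. The signals and ratios given for single genes are not corrected for this shift, so rises read larger and falls smaller than after scaling. The number of calls also depended on the pseudocount, with 110 higher and 101 lower at a pseudocount of 1. The authors' deposited table of probe sets with at least a 2-fold difference held 694 higher and 450 lower in induced arrays. Of its 691 higher and 450 lower probe sets tested here, 492 and 299 were called in the same direction and 0 in the opposite one. Both come from the same arrays, so more overlap than the 28.9 and 6.10 of independent lists was bound to arise and lends no support.

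Erythroid genes fell together. Of 28 members tested, 20 fell and 1 rose (24 and 2 adjusted over the list alone; 8 and 0 at a pseudocount of 1), and the list's median log2 change was -0.56 (camera, adjusted p = 1.78e-27). With an estimated correlation between genes the adjusted p was 0.104. Besides Tfrc and Slc4a1, the blood group gene Ermap fell from 55.6 ± 1.02 to 15.6 ± 1.94 and the membrane skeleton gene Epb41 from 54.7 ± 0.51 to 18.6 ± 1.92. The member called higher was the beta globin gene Hbb-b2, read by a dim probe set (adjusted p = 0.0220), which lost the call without any 1 of 5 arrays (up to 0.0985 without control 2) and for which the authors' ratio of control over induced was 0.963. The brightest beta globin probe set, which is shared with Hbb-b2, was not called (adjusted p = 0.959). Haem biosynthesis genes fell in 9 of 15 and rose in 0 (13 and 0 adjusted over the list alone, 3 fell at a pseudocount of 1; adjusted p = 5.15e-19; adjusted p = 0.104 with an estimated correlation). Fech, the enzyme of the pathway that inserts the iron, fell from 86.8 ± 12.5 to 35.5 ± 1.90.

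Granulocyte genes moved in both directions. At a pseudocount of 1 the called members were 0 promyelocyte genes, 2 mature neutrophil genes, and 2 rises and 1 fall of eosinophil, basophil and mast cell markers. Among primary granule genes of promyelocytes 5 of 10 fell and 0 rose (6 and 0 adjusted over the list alone; adjusted p = 2.88e-07; adjusted p = 0.104 with an estimated correlation). Mpo, myeloperoxidase, fell from 149.2 ± 12.7 to 71.3 ± 13.1, and Prtn3, proteinase 3, from 17.2 ± 0.40 to 6.10 ± 1.81. Mature neutrophil genes rose in 8 of 14 and fell in 0 (11 and 1 adjusted over the list alone; adjusted p = 6.32e-08; adjusted p = 0.214 with an estimated correlation). Slpi, a protease inhibitor, rose from 32.9 ± 6.42 to 81.3 ± 14.1, and Il1r2, the decoy receptor of interleukin 1, rose at least 2.88-fold from background. Without control 1, 4 of the mature neutrophil genes were called higher and without control 2, 5; after quantile normalization 7 rose and 1 fell. Of 11 eosinophil, basophil and mast cell markers, 5 rose and 1 fell (adjusted p = 0.0334; adjusted p = 0.390 with an estimated correlation), and the one that fell, Mcpt8, is a basophil protease. That list lost its call without control 2 (adjusted p = 0.0985), control 3 (0.0603) or induced 2 (0.0676), and 3 members rose without any 1 control. Secondary and tertiary granule genes of neutrophils had 1 rise and 1 fall among 15 (adjusted p = 0.540), and were called lower after quantile normalization (adjusted p = 9.10e-06). Leaving out 1 array gave 2 falls without control 2 or induced 1 and 0 without any other.

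Markers of B cells, plasma cells, dendritic cells and macrophages rose in part. At a pseudocount of 1 the called rises were 1 B cell, 0 plasma cell, 1 dendritic cell, 1 monocyte and macrophage and 2 megakaryocyte and platelet markers. Of 21 mature B cell markers 6 rose and 0 fell (7 and 0 adjusted over the list alone; adjusted p = 7.37e-05; adjusted p = 0.214 with an estimated correlation). Cd74, the invariant chain of MHC class II, rose from 33.0 ± 5.59 to 106.0 ± 21.4, H2-Ab1 from 6.57 ± 1.65 to 27.2 ± 3.00, and the immunoglobulin heavy chain Ighm from 13.3 ± 2.26 to 33.6 ± 4.2. Plasma cell markers rose in 5 of 12 (adjusted p = 0.00134; adjusted p = 0.214 with an estimated correlation), with the light chain Igk at 113.7 ± 14.8 and 252.4 ± 35.3, and 3 rose without control 2 or induced 3. Dendritic cell markers rose in 5 of 14 (adjusted p = 7.66e-04; adjusted p = 0.157 with an estimated correlation), 4 of them (Cd74, H2-Aa, H2-Ab1 and H2-Eb1) also members of the B cell list, and 1 member fell without control 1 or induced 2. Monocyte and macrophage markers rose in 7 of 20 and fell in 2 (adjusted p = 0.0152; adjusted p = 0.314 with an estimated correlation). Of these, 4 rose without any 1 control or induced 3 and 3 without induced 1, and 1 fell without control 2 or induced 3. The complement gene C1qb rose from 4.87 ± 2.05 to 24.7 ± 2.57, and F13a1, coagulation factor XIII, fell from 31.0 ± 5.46 to 6.40 ± 2.0. Megakaryocyte and platelet markers rose in 4 of 19 and fell in 1 (adjusted p = 0.0152; adjusted p = 0.434 with an estimated correlation; adjusted p = 0.0803 without control 2), and 0 fell without control 1, control 3, induced 2 or induced 3.

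Collagens and the AP-1 family did not shift as lists, while single members rose. Col1a2 rose from 6.20 ± 0.30 to 18.0 ± 2.83 and Col1a1 from 23.4 ± 7.89 to 50.6 ± 10.5, the 2 called among 16 collagens (2 and 0 adjusted over the list alone; adjusted p of the list = 0.746). Col1a1 lost its call without control 3 (adjusted p = 0.0554). Other matrix genes had 3 rises and 1 fall among 24 (adjusted p = 0.540). Sparc, a collagen-binding matrix protein, rose from 9.67 ± 2.60 to 46.6 ± 7.15, and Fn1, fibronectin, fell from 16.2 ± 1.47 to 1.87 ± 0.32. Profibrotic growth factors and receptors rose in 3 of 22 (4 and 0 adjusted over the list alone; adjusted p = 0.0277; adjusted p = 0.268 with an estimated correlation). Of these, Lgals3, galectin 3, rose from 30.7 ± 5.10 to 64.4 ± 6.80. Tgfbr2 and Smad3 were called with all 6 arrays and lost their call without control 3 (adjusted p = 0.123 and 0.159) and without other arrays, and 1 of the profibrotic genes was called without control 3, induced 1 or induced 3. In the AP-1 family 2 of 17 rose, Fos and Jdp2 (adjusted p of the list = 0.771), and Jdp2 lost its call without induced 1 (adjusted p = 0.0544) or induced 3 (0.0520). In that family 1 member fell without control 3. After quantile normalization 1 AP-1 family member rose and 2 fell. The counts were 2 and 1 when scaled to 1 trimmed mean, and 1 and 1 when scaled to 1 median. Genes known as AP-1 targets rose in 6 of 24 (9 and 0 adjusted over the list alone; adjusted p = 0.00405; adjusted p = 0.268 with an estimated correlation). Without induced 1, 3 of these were called higher. At a pseudocount of 1 the called members were 2 AP-1 targets, 0 profibrotic genes, 0 collagens, 1 osteoblast marker and 1 AP-1 family member. Besides Dusp1 and Spp1, the haem oxygenase Hmox1 rose from 8.37 ± 1.29 to 23.7 ± 3.90. Osteoblast markers rose in 3 of 11, namely Spp1, Col1a1 and Col1a2 (adjusted p = 0.0278; adjusted p = 0.390 with an estimated correlation), and lost the call without control 1 (0.0605), control 3 (0.204) or induced 3 (0.0744).

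Inflammatory and stress genes rose in part. At a pseudocount of 1 the called rises were 4 cytokines and chemokines, 2 NF-kappaB targets, 0 heat shock and 0 unfolded protein response genes and 1 apoptosis regulator. Of 22 inflammatory cytokines and chemokines 9 rose and 0 fell (9 and 0 adjusted over the list alone; adjusted p = 4.92e-06; adjusted p = 0.214 with an estimated correlation). Ccl6 rose from 72.3 ± 7.72 to 140.3 ± 18.4, and Cxcl2, a neutrophil attractant, rose at least 5.90-fold from background. NF-kappaB targets rose in 4 of 21 and fell in 1, Tnfaip2 (adjusted p = 0.0342; adjusted p = 0.214 with an estimated correlation). That list lost its call without control 1 (0.0641), control 2 (0.0642), control 3 (0.0927) or induced 2 (0.0533), and 2 members rose without control 1 or control 3. Heat shock genes rose in 7 of 14 (10 and 0 adjusted over the list alone; adjusted p = 1.53e-08; adjusted p = 0.206 with an estimated correlation), with Hsph1 rising from 41.8 ± 3.98 to 105.4 ± 14.5. Of these, 4 rose without induced 1 and 3 without induced 3. Glucocorticoid and stress responsive genes rose in 3 of 15, Dusp1, Sgk1 and Ddit4 (adjusted p = 4.44e-04; adjusted p = 0.214 with an estimated correlation). Unfolded protein response genes rose in 2 of 19 and fell in 1 (adjusted p = 0.0278; adjusted p = 0.390 with an estimated correlation), a call lost after quantile normalization (adjusted p = 0.344), without control 2 (0.0803) and without induced 1 (0.117), and 0 fell without control 2, control 3, induced 2 or induced 3. Apoptosis regulators rose in 3 of 24 (adjusted p = 0.0151; adjusted p = 0.324 with an estimated correlation).

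Genes of protein synthesis and energy metabolism rose in part. At a pseudocount of 1 the called members were 0 cytosolic ribosomal, 0 oxidative phosphorylation, 1 mitochondrial ribosomal and 1 glycolysis gene, and 1 fall and 0 rises of cell cycle genes, while the first 2 lists were still called (camera, adjusted p = 8.76e-10 and 2.33e-06). Cytosolic ribosomal protein genes rose in 21 of 27 (23 and 0 adjusted over the list alone; median log2 change 0.72; adjusted p = 4.81e-23; adjusted p = 0.214 with an estimated correlation). Without control 2, 12 of the ribosomal genes were called higher. Rps4x went from 174.5 ± 18.1 to 358.8 ± 47.8 and Rpl6 from 138.7 ± 9.66 to 275.1 ± 25.8. Oxidative phosphorylation genes rose in 14 of 32 (adjusted p = 1.96e-13; adjusted p = 0.157 with an estimated correlation), with Atp5b going from 26.6 ± 6.66 to 60.4 ± 1.87. The count was 7, 5 and 6 without control 1, 2 and 3, 7 without induced 1 and 9 without induced 3. After quantile normalization 15 ribosomal and 5 oxidative phosphorylation genes were called higher. Mitochondrial ribosomal protein genes rose in 4 of 32 (adjusted p = 2.83e-04; adjusted p = 0.268 with an estimated correlation), in 1 without any 1 control or induced 3, and in 7 without induced 2. Glycolysis and hypoxia genes rose in 6 of 22 (adjusted p = 0.00508; adjusted p = 0.324 with an estimated correlation), among them Slc2a1 from 5.27 ± 1.81 to 19.1 ± 2.40, and 1 fell without control 1. Beside these lists, the Gapdh control probe sets read 16.5% ± 5.50 of their 3' signal at the 5' end in controls and 27.5% ± 1.58 in induced arrays (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 arrays can give). Cell cycle genes fell in 4 of 35 and rose in 2 (adjusted p = 7.87e-05; adjusted p = 0.324 with an estimated correlation), with Rrm2 falling from 544.0 ± 38.0 to 256.5 ± 37.3 and Mcm6 rising from 14.5 ± 3.29 to 33.7 ± 3.84; 1 rose without any 1 array other than induced 2, and after quantile normalization 12 fell and 1 rose.

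**Figure D2:**
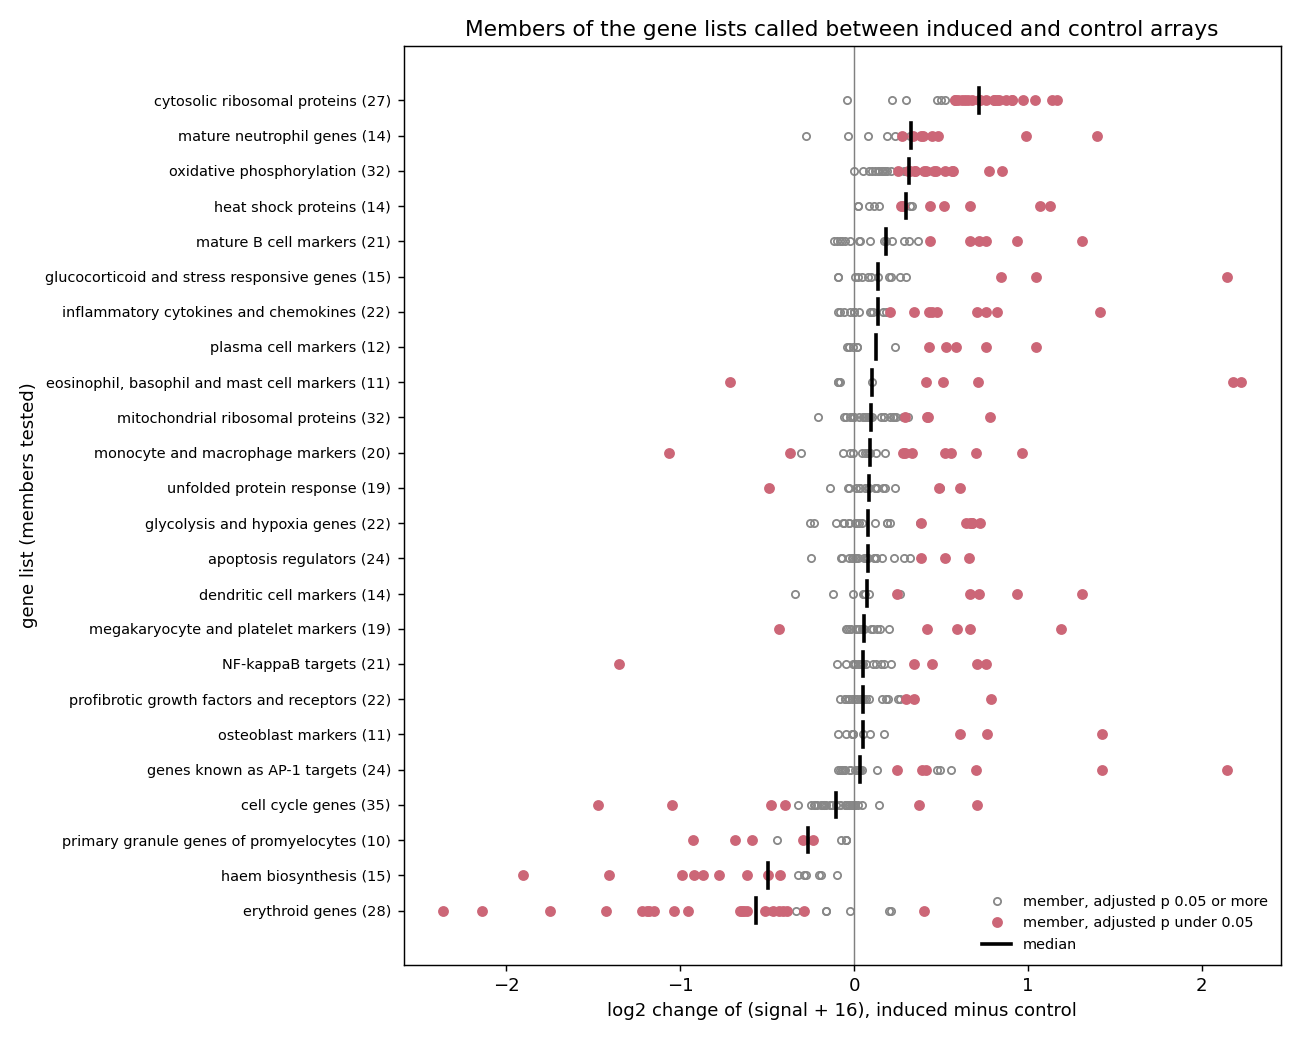
Log2 change of (signal + 16), induced minus control, of the tested members of the 24 gene lists with an adjusted p under 0.05, ordered by median. Filled points are members with an adjusted p under 0.05, open points the other members, black lines the medians; erythroid genes have the lowest median, -0.56, and cytosolic ribosomal proteins the highest, 0.72.

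The other 22 lists tested were not called by camera at its preset correlation, with the smallest adjusted p at 0.113 for p53 targets. They were the lists of AP-1 family members, collagens, other matrix genes and secondary granule genes given above, together with immediate early genes, matrix proteases, marrow stromal, osteoclast, endothelial, adipocyte and skeletal muscle markers. Stem and progenitor, pro-B and pre-B, and T and NK cell markers were also among them, as were interferon-stimulated, checkpoint, Hedgehog, Wnt, amino acid response, NRF2 and cholesterol genes. Camera sets a list against the other genes tested, and 13232 of 31523 probe sets tested were at background in both groups. Probe sets with mean signal over 10 had a median log2 change of 0.24. Lists of expressed genes can thus be called higher with smaller medians. The smallest were 0.03 for AP-1 targets and 0.05 for osteoblast, profibrotic and NF-kappaB genes. Megakaryocyte markers had 0.06 and dendritic cell markers 0.07. Further examples were 0.08 for apoptosis and glycolysis genes, 0.09 for unfolded protein response and 0.10 for mitochondrial ribosomal genes. Of all 16239 genes tested, 835 were higher and 296 lower. None of the 24 called lists kept its call with an estimated correlation (0 of 24). Under fry, which asks whether the members of a list move one way, 20 of the 24 kept it, and it was lost by megakaryocyte (adjusted p = 0.0608), cell cycle (0.0879), unfolded protein response (0.0879) and mitochondrial ribosomal genes (0.0557). With fry 2 further lists were called, immediate early genes (0.0311) and marrow stromal markers (0.0396). Without a filter on low values, profibrotic (0.0549), osteoblast (0.159) and eosinophil genes (0.194) lost their call, and the last did so at a pseudocount of 64 (0.0730) and with array weights (0.0508). Osteoblast genes lost it with the replicate block (0.0536), and unfolded protein response genes at a pseudocount of 1 (0.0534), with an intensity trend (0.0529) and when scaled to 1 trimmed mean (0.0699) or to 1 median (0.226). The intensity trend added immediate early genes (0.00570) and p53 targets (0.0478), and the mean of all probe sets of a gene added p53 targets (0.0422). With the filter at the 60th percentile 7 lists lost their call (adjusted p from 0.0668 to 0.196), namely profibrotic, monocyte and macrophage, eosinophil, megakaryocyte, NF-kappaB, unfolded protein response and apoptosis genes. At a trimmed mean of 500, 9 lists lost it (0.0861 to 0.153), namely AP-1 targets, profibrotic, osteoblast, monocyte and macrophage, eosinophil, plasma cell, unfolded protein response, glycolysis and apoptosis genes. Of 4 sex-linked genes tested, 1 rose and 1 fell, with 0 called at a pseudocount of 64 or without a filter. Xist, expressed from the inactive X chromosome of females, rose from 0.80 ± 1.21 to 7.13 ± 2.41 (adjusted p = 0.0105; 0.0545 without control 3). Its other tested probe sets lay near background and were not called (limma, adjusted p = 0.536 and 0.612). Ddx3y, on the Y chromosome, fell from 6.17 ± 1.46 to 2.63 ± 0.31 (adjusted p = 0.0394), and lost its call without any 1 of 5 arrays, with adjusted p up to 0.144 without control 3. The other tested probe sets of Ddx3y lay at background and were not called (limma, adjusted p = 0.407 and 0.958). Eif2s3y, also Y-linked, had 10.0 ± 3.30 and 4.70 ± 0.70 (adjusted p = 0.0617). Y-linked Kdm5d had 1.77 ± 1.70 and 1.57 ± 0.42 (adjusted p = 0.969), and Uty lay under the filter at background.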

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

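All of the tests in this part were chosen after the results had been seen. Both scaling tests first counted called members against a bound of 10 under 4 other scalings, without the trimmed mean of 500; with it the count is 0 and that rule gives the opposite answer. The list median over 5 scalings replaced the count after both were seen, because at a trimmed mean of 500 no probe set of any list was called. The control probe sets, which no comparison of the report tests as genes, read more of the 5' end of Gapdh in induced arrays (27.5% of the 3' signal) than in controls (16.5%), and likewise of Actb (19.9% against 13%). For both the exact permutation p was 0.1, two-sided, the smallest that 3 against 3 arrays can give. Control 2 stood apart from the other arrays, with 346 signals of 0 against 4653 to 7818 and 31.6% of signals over background against 19.3% to 22.9%. Its correlations with the other controls were 0.962 and 0.966, against 0.976 between those 2. The cause was not tested.

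The fall of erythroid and haem genes was weighed against scaling and cell makeup. The list's median log2 change stayed below 0 under 5 other scalings. It was -0.56 (bootstrap standard error over members 0.13) with arrays centred on the median and -0.73 (0.16) after quantile normalization. At a trimmed mean of 500 it was -1.88 (0.16), on another scale, since that raises the signals against the pseudocount. Probe sets with mean signal over 10 had a median change of 0.24 as deposited and 0.06 after quantile normalization. The values argue only against scaling of that size as the whole cause, and the standard errors take genes as independent. At least 20 of the 28 genes were called lower under 4 of these scalings and 0 at a trimmed mean of 500. The log2 changes of 16 members with mean signal over 10 had an SD of 1.03 at a pseudocount of 1. The median standard error of 1 gene was 0.38. The changes ran from -2.74 for Rhd to 0.93 for Hbb-b2, the dim probe set named in the report. This spread does not decide on an equal loss of all erythroid cells, since members also expressed in other cells would fall less. Mature neutrophil genes had a median log2 change of 0.33 and promyelocyte genes one of -0.27, a difference of 0.60 (permutation p = 1.1e-04, two-sided). That permutation exchanged genes between the 2 lists. It takes genes as independent and does not measure the spread between pools. The opposite signs argue against a lower erythroid share as the only cause of the granulocyte changes, without a test over pools. They do not bear on why the erythroid genes fell. Open are an equal loss of all erythroid cells, a loss of some erythroid stages, a change within cells and compression of bright probe sets. Also open are an effect of doxycycline itself and the difference in 5' coverage given above, which runs with the groups.

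The rise of ribosomal protein genes was weighed against scaling and RNA quality. The list's median log2 change stayed above 0 under 5 other scalings. The lowest was 0.33 (bootstrap standard error over members 0.05) after quantile normalization, against 0.72 as deposited. That argues against scaling as the whole cause, though part of the rise depends on it and the standard error takes genes as independent. At least 15 of the 27 genes were called higher under 4 of these scalings and 0 of 26 at a trimmed mean of 500. The share of Gapdh signal at the 5' end was 11 percentage points higher in induced arrays. This difference runs with the groups, so RNA quality or amplification and induction cannot be told apart for this list. The same holds for the other lists and genes compared here.

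The changes of Xist and Ddx3y may come from different numbers of female and male mice in the pools. Of the Y-linked genes only Ddx3y was called lower, while Eif2s3y missed the threshold, Kdm5d was not called and Uty was at background. A rise of Xist with a fall of Ddx3y is the direction of a different sex makeup. Those values prompted the explanation and do not test it. Of 3 genes that escape X inactivation and had a mean signal over 2, after quantile normalization 0 had all induced arrays above the controls, 1 (Kdm5c) had them all below, and 2 (Ddx3x and Kdm6a) overlapped. As deposited, Ddx3x was called higher, from 59.8 ± 9.94 to 90.3 ± 12.5 (limma, adjusted p = 0.0252). Kdm5c (0.0746) and Kdm6a (0.652) were not called as deposited. With 3 genes that differ in direction these values do not decide it. No biological explanation was tested, and the sex makeup of the pools stays open.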

How the results depend on the processing

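No called value changed direction past its threshold under any alternative. Secondary and tertiary granule genes, not called as deposited (median log2 change 0.02), were called lower in 2 scalings. Their median was -0.12 after quantile normalization (camera, adjusted p = 9.10e-06) and -0.12 when scaled to 1 median (0.00321). The 24 leading genes kept their calls under every alternative fitted to single probe sets except the plain per-gene test, which called 7 of them, and scaling to a trimmed mean of 500, which called 0. Scaling to 1 trimmed mean, to a trimmed mean of 500 and to 1 median were chosen after seeing the data. Counts of probe sets moved more, from 1320 higher and 427 lower. A pseudocount of 1 gave 110 and 101, no filter 595 and 246, the plain per-gene test 22 and 26, and the authors' p-values 339 and 274. A pseudocount of 64 gave 801 higher. Quantile normalization gave 853 lower, and scaling to 1 median of probe sets with mean signal over 10 gave 866 lower. Scaling to a trimmed mean of 500 gave 0 and 0 with limma, with 3308 probe sets at an unadjusted p under 0.05. It raises the signals against the pseudocount, as a pseudocount of 1 also does; for the other settings the cause was not tested. Without a filter the called ribosomal genes went from 21 to 10, oxidative phosphorylation genes from 14 to 3, heat shock genes from 7 to 3, mature neutrophil genes from 8 to 3 and cytokines from 9 to 4. The plain per-gene test called 4 erythroid and 0 ribosomal genes, and the authors' p-values 14 and 7. Leaving out 1 array gave 879 to 1362 higher, the fewest without control 2, and 277 to 437 lower, the fewest without induced 3. The log2 change of Jun ranged from 0.08 to 0.18 without 1 array and was not called under any alternative. Of 24 called lists, scaling to a trimmed mean of 500 left 15 calls, the filter at the 60th percentile 17 and an estimated correlation 0; leaving out 1 array gave 20 to 23. Same-numbered arrays did not deviate together (correlations across probe sets of -0.07, 0.04 and -0.03), so the numbers were not taken as pairs; with the replicate block 1052 probe sets were higher, 325 lower and 23 lists called. Most signals lay at or under background (76.9%), where no fold can be read.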

Other observations

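Globin probe sets did not move together; they were singled out after their values were seen. Embryonic Hbb-bh1 rose in each of its 3 probe sets, from 0.60 ± 0.79 to 12.4 ± 3.20 (at least 6.22-fold), from 0.43 ± 0.59 to 14.6 ± 4.25 (at least 7.30-fold) and from 1.47 ± 0.55 to 11 ± 1.39. The embryonic Hbb-y and Hba-x stayed at background in both groups. The 3 bright probe sets shared by the adult alpha globin genes were lower in induced arrays, by 2.05-, 1.69- and 1.68-fold, for example 2825 ± 171 in controls and 1673 ± 224 in induced arrays. The brightest beta globin probe set, shared by several genes, had 4871 ± 404 and 4924 ± 276 (adjusted p = 0.959). Probe sets of near-identical globin genes can read each other's transcripts.

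Outside the lists, further rises by the log2 change of (signal + 16) included Cd53, a leukocyte tetraspanin, with 347.5 ± 32.1 in induced arrays (limma, adjusted p = 9.09e-05), and B2m, the light chain of MHC class I, with 715.1 ± 103.6 (adjusted p = 1.28e-04). Further falls on that scale included Tspan33, 6.76-fold lower, Tfdp2, 6.73-fold, and the cell cycle phosphatase Cdc25b, 4.33-fold. These genes were picked after their values were seen, from the 10 largest changes per direction on that scale that no list holds; by ratio some of them pass genes of the report.

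Grouping the 6 arrays otherwise gave fewer calls, in tests chosen after the counts had been seen. The real grouping called 1747 probe sets and the highest of the other 9 called 0; only 1 of the 10 splits, the real one, reached the real count. For gene lists the real grouping called 24 and the highest other 7, again 1 of 10. With 10 splits no share under 0.1 can be reached, too few for this test. Each of the other 9 splits also mixes both groups, so the group difference widens the spread within them. Fewer calls there would follow whatever caused the difference.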
